A study of Arabidopsis thaliana with 12 samples.

How the data were processed

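Total RNA came from the basal 4 cm of Arabidopsis thaliana inflorescence stems that stood 12 to 17 cm tall, taken from plants kept in a glasshouse at 22 °C under 16 h of light and 8 h of dark, per the labels' protocols. Labelled cRNA was made from 200 ng of RNA with a 3′ IVT kit and each sample was hybridised to its own Affymetrix array, so a probe set reads the 3′ part of its transcript. The 12 arrays fall into 4 groups of 3, named here by their labels: WT (ecotype Col-0), C3H14-OE, C3H15-OE and c3h14c3h15, the double mutant. The sample titles call the 3 arrays of a group biological replicates. Whether the arrays of an overexpressor group are separate transgenic lines or separate plants of 1 line is left open by the labels' wording, so the p-values measure the spread between these samples, whichever it was.

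The deposited values are normalized intensities on a linear scale, which the authors made with RMA, per the submitters' processing notes; the version and settings are not given in the sources used here. Log2 of each value was taken before any test, as planned for a table that turned out to be linear. The log2 medians of the 12 arrays lay between 5.65 and 5.84. The table holds 22810 probe sets; 64 control probe sets were left out, and 22746 were tested with no filter on dim signals. For arrays, the number of arrays limits the precision. No 2 arrays were identical, and the correlation of log2 values between arrays ran from 0.953 to 0.995.

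Genes were named only from the platform's annotation table, with symbols updated through the RefSeq gene table of assembly TAIR10.1. Of the tested probe sets, 13513 had 1 gene, 503 had several and 8730 were unlisted and stay unnamed here; 13436 of the 1-gene probe sets matched the RefSeq table and 77 kept their older name. The annotation is uneven. Among protein-coding genes with a published symbol 14.6% had a 1-gene probe set, against 63.3% of those known only by a locus number. The probe set of C3H14 (AT1G66810) is named and that of C3H15 (AT1G68200) is unnamed here. No coordinates are given, since no build was named for the array.

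All tests used limma (version 3.58.1 under R 4.3.3). One linear model with a mean per group was fitted to all 12 arrays (8 residual degrees of freedom, 3.61 prior degrees of freedom), and 5 contrasts were taken: each of the other 3 groups against WT, C3H14-OE against C3H15-OE, and the mean of both overexpressors against the double mutant. P-values were adjusted by Benjamini-Hochberg over the 22746 probe sets, with a threshold of 0.05, and every adjusted p for a gene comes from this limma fit. Fold changes are log2 differences of group means, with moderated standard errors (SE). Tested on simulated data with the real spread of each probe set for C3H15-OE against WT, the fit recovered 76.5% of 200 changed probe sets at 2-fold and 97.5% at 4-fold. There were 8 false calls at each size among the unchanged rest of the 22746 probe sets. The simulated noise was independent between probe sets, so deviations that many probe sets of an array share were not covered.

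Genes were chosen by a rule fixed before the data were examined, as were the designs, 24 gene lists and the alternative settings. For each comparison with WT the rule takes the 10 largest rises and 10 largest falls among 1-gene probe sets past the threshold whose arrays do not overlap between the groups, all of them where fewer qualify. For the other 2 contrasts it takes 5 each way, for opposite responses up to 10, and for each list up to 4 members past the threshold or, with none, up to 2 as values; members counted may also be named when 5 or fewer passed. Of the 323 list members 40 had a named probe set. The 7 lists with 3 or more such members were tested with camera (preset inter-gene correlation of 0.01) on the brightest probe set per gene, adjusted over these lists within a contrast. The adjustment was first made over fixed and added lists together and then apart, as set out beforehand, with no change in the calls of fixed lists. Another 9 lists had 1 or 2 members, given as values, and 8 had none. Camera was also run with an estimated correlation, and fry was run beside it. After the annotation was seen and before any expression value was tested, 24 further lists and families were added.

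Replicate numbers were not taken to pair arrays: of 18 pairs of arrays with the same number 4 had within-group deviations that correlated over 0.1. Comparisons against WT share the WT arrays, so unchanged groups were simulated in 100 draws from the within-group deviations. The alternatives were a second quantile normalization, cyclic loess, leaving out the dimmest 40% of probe sets, fitting only the arrays compared, the replicate number as a block, an intensity trend with robust eBayes, array weights, 1-gene probe sets without shared suffixes, 1 probe set per gene, an added 2-fold threshold, and leaving out each array in turn. Leaving out 3 arrays that stood apart was added after the data were seen.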

Results

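C3H14 and C3H15 are a pair of related tandem CCCH zinc finger proteins, and the series set plants that overexpress either gene and a double mutant that lacks both against wild type, with secondary wall formation and pollen formation as its stated themes. Transcript levels were measured on 12 arrays of basal inflorescence stem, 3 per group. On the first principal component, which held 44.5% of the variance, the C3H15-OE arrays scored 27.6 to 48.1 and the double mutant arrays -57.1 to -18.5. The array labelled C3H14-OE replicate 3 scored 40.8, among the C3H15-OE arrays, while the other C3H14-OE arrays scored 14.6 and 8.1. WT replicate 2 (-5.2) lay nearer the overexpressors than the other WT arrays did (-24.2 and -31.3), and mutant replicate 1 (-18.5) lay nearer them than the other mutant arrays.

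**Figure D1:**
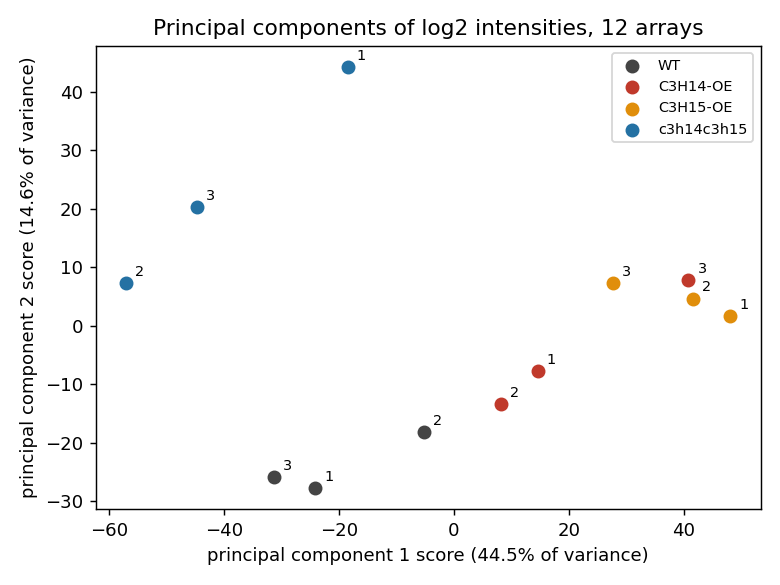
Scores of the 12 arrays on principal components 1 and 2 of the log2 intensities, coloured by labelled group, with replicate numbers beside the points and the share of variance on each axis. C3H14-OE replicate 3 lies at 40.8 on component 1, between C3H15-OE arrays at 27.6 and 48.1.

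C3H14 itself was measured first, as a check of the labels. Its log2 intensity was 6.85 ± 0.67 (SD, n = 3) in WT, 8.20 ± 1.03 in C3H14-OE, 5.52 ± 0.42 in C3H15-OE and 6.35 ± 0.24 in the double mutant. On the arrays labelled C3H14-OE it read 8.43, 9.10 and 7.07, and the last of these, replicate 3, lay within the WT range of 6.12 to 7.43. The rise of 1.34 log2 units in C3H14-OE did not pass the threshold (SE 0.45, adjusted p = 0.258), nor did the difference of -1.34 in C3H15-OE (SE 0.45, adjusted p = 0.0993) or of -0.50 in the mutant (SE 0.45, adjusted p = 0.583). C3H14 was 2.68 log2 units higher in C3H14-OE than in C3H15-OE, just short of the threshold (SE 0.45, adjusted p = 0.0553). Without C3H14-OE replicate 3 this difference (3.24) and that of C3H15-OE from WT (-1.34) passed, while the rise in C3H14-OE did not (1.91). Without C3H15-OE replicate 3 the difference between the overexpressors passed as well (2.91). A 3′ probe set can still read a transcript interrupted elsewhere, and where the mutations lie was not analysed here, so the mutant level checks nothing. C3H15 was not named on the array, so the groups keep the names of their labels, and each direction given for C3H14-OE or C3H15-OE below rests on those labels.

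**Figure D2:**
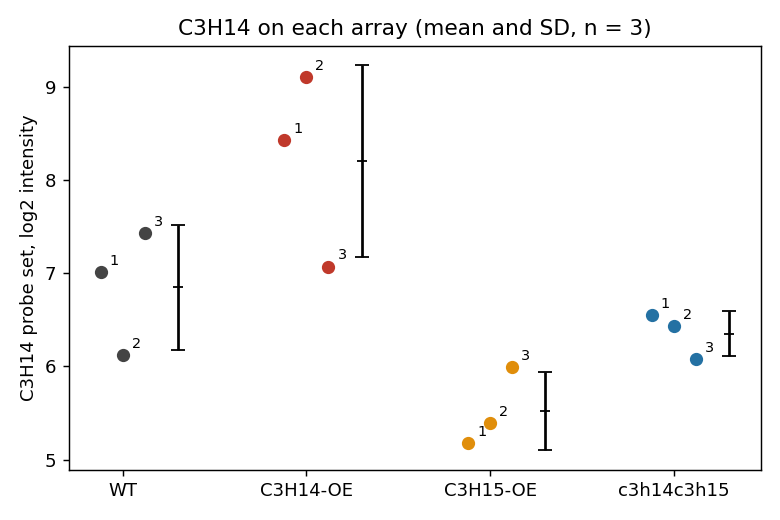
Log2 intensity of the C3H14 probe set on each array, by labelled group, with replicate numbers; the bars give the mean and SD of the 3 arrays. C3H14-OE replicates 1 and 2 lie above every WT array and replicate 3, at 7.07, lies among them.

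The arrays labelled C3H14-OE asked what raised C3H14 does to stem transcripts. AT4G24350 rose by 2.24 log2 units (SE 0.32, adjusted p = 0.0416). AT1G43590 (-1.81, SE 0.22, adjusted p = 0.0139), AT5G02580 (-1.71, SE 0.20, adjusted p = 0.0139) and AT2G42770 (-1.15, SE 0.09, adjusted p = 0.00068) fell. All 4 also changed in the same direction in C3H15-OE (1.44, -1.74, -1.27 and -1.18, in the same order). In the mutant AT5G02580 fell as well (-1.03, adjusted p = 0.0151) and AT1G43590 stood at -0.82 (adjusted p = 0.0501). AT2G42770 rose there (0.72, adjusted p = 0.00293) and AT4G24350 stood at -0.24. These comparisons share the WT arrays. The 4 were the only named genes to pass in C3H14-OE. Of the defence and wounding genes, WRKY53, a transcription factor of senescence and defence, stood at 1.23 (SE 0.34, adjusted p = 0.199), ZAT10 at 1.92 (SE 0.48, adjusted p = 0.184) and the calmodulin-like CML38 at 2.17 (SE 0.84, adjusted p = 0.305). In all, 4 probe sets were higher and 6 lower than in WT, each by over 2-fold, while 3181 had an unadjusted p under 0.05 against 1137 expected by chance. All 4 xylan genes lay below WT, IRX15 at -0.77 and IRX15L at -0.75; 0 passed over all probe sets and 3 did when adjusted over the list alone. The list shifted down by camera (mean -0.54, adjusted p = 0.028), as did photosynthesis (mean -0.35, adjusted p = 0.028). With an estimated correlation the adjusted p was 0.728 for each list, with array weights 0.0702 for each, and by fry 0.24 for xylan and 0.296 for photosynthesis. In photosynthesis LHCB4.1 stood at -0.47 and PSAE1 at -0.49. Of its 6 members 0 passed over all probe sets and 1, LHCB4.1, passed adjusted over the list alone. The other 5 tested lists did not pass and had 0 members past the threshold: cold and abscisic acid (adjusted p = 0.815), lignin (0.815), flavonoids (0.976), the tapetum and pollen wall (0.976) and wall loosening (0.976). Most named lignin genes and all named tapetum and pollen wall genes were dim, as given below for C3H15-OE. Without C3H14-OE replicate 3 there were 2 calls, both among the 10, and neither xylan (mean -0.50, adjusted p = 0.0766) nor photosynthesis (mean -0.16, adjusted p = 0.321) passed. The same held without WT replicate 3 (0.149 for each list) and, for xylan, without C3H14-OE replicate 1 (0.0935). The counts higher and lower were 1 and 2 without WT replicate 1 or WT replicate 3, 0 and 1 without C3H14-OE replicate 1, 19 and 37 without mutant replicate 1 and 12 and 12 without mutant replicate 2. The higher count alone was 12 without C3H14-OE replicate 2, 7 without C3H15-OE replicate 1 and 1 without mutant replicate 3. The lower count alone was 12 without WT replicate 2.

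The C3H15-OE arrays differed widely from WT, with 702 probe sets higher and 811 lower, of which 273 and 345 also passed 2-fold. Of the 20 listed genes of the synthesis of xylan, the main hemicellulose of secondary walls, 4 were named on the array and 3 of these fell. IRX15L changed by -1.26 (SE 0.26, adjusted p = 0.0204), IRX15 by -1.17 (SE 0.24, adjusted p = 0.0205) and IRX10 by -0.91 log2 units (SE 0.23, adjusted p = 0.0394). IRX10L stood at -0.07, and with an estimated correlation the list did not pass (adjusted p = 0.364). WRKY53 rose by 2.0 (SE 0.34, adjusted p = 0.0103), and AT2G43570, a chitinase listed under the symbol CHI, rose by 3.55 (SE 0.93, adjusted p = 0.0432). The tubulin TUB1 changed by -2.46 (SE 0.56, adjusted p = 0.0281) and the xyloglucan endotransglucosylase XTH16 by -2.12 (SE 0.44, adjusted p = 0.0202). AT2G14900, of a gibberellin-regulated family, changed by -2.32 (SE 0.57, adjusted p = 0.0364).

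The other large rises in C3H15-OE were AT5G55450 (3.12), AT5G39670 (3.10), QQS (3.04), which acts in starch metabolism, AT5G52760 (2.89), MSRB9 (2.67), a methionine sulfoxide reductase, AT4G00700 (2.58), AT2G41480 (2.55), AT3G13950 (2.50) and AT1G06620 (2.41). Their adjusted p-values ran from 0.000877 for MSRB9 to 0.0176 for AT2G41480. The other large falls were AT5G22580 (-3.69), AT4G23820 (-2.94), a pectin lyase-like gene, AT2G05540 (-2.74), AT1G13670 (-2.70), AT2G19970 (-2.69), AT1G50040 (-2.55), AT1G31710 (-2.42) and AT5G57785 (-2.27), with adjusted p-values from 0.000466 for AT1G50040 to 0.0423 for AT1G31710.

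By list, the 4 xylan genes shifted down in C3H15-OE (mean -0.85, camera adjusted p = 0.012), with 3 lower both over all probe sets and adjusted over the list alone; with an estimated correlation the adjusted p was 0.364 and by fry 0.0269. Photosynthesis passed narrowly (mean -0.39, adjusted p = 0.0486, or 0.462 with an estimated correlation and 0.117 by fry) with 0 of 6 members past the threshold either way; SBPASE, a Calvin cycle enzyme, stood at -0.62 and PRK at -0.51. Its call was lost, with adjusted p from 0.0539 to 0.207, without WT replicate 2 or 3, C3H15-OE replicate 1 or 2, or mutant replicate 1 or 3, and with the replicate number as a block (0.0534). Of the 3 cold and abscisic acid genes, COR15B fell by 1.04 (adjusted p = 0.023), 1 member passing both ways. The list did not pass (camera adjusted p = 0.0722, or 0.364 with an estimated correlation), though it did by fry (0.0343), without C3H14-OE replicate 3 (0.0239), without C3H15-OE replicate 3 (0.0198) and after cyclic loess (0.0412). Of the 4 wall loosening genes XTH16 fell and 3 did not pass over all probe sets; adjusted over the list alone XTH16 and EXPA8 were lower and EXPA4 higher, and the list did not pass (adjusted p = 0.265). Lignin (PRX52 at 1.13 and PRX72 at -0.20), the tapetum and pollen wall (ATA27 at 0.11 and A9 at 0.10) and flavonoids (UF3GT at -0.31 and DFR at 0.21) had 0 members past the threshold and adjusted p-values of 0.654, 0.654 and 0.752. In WT, PRX52 (2.77), PRX72 (2.29) and all 6 tapetum and pollen wall genes (1.96 to 3.55) were dim against array medians of 5.65 to 5.84. Only 3 of 22 lignin and 6 of 29 tapetum and pollen wall members were named. In every comparison these lists thus say little about lignin or pollen wall genes at large. Single members of other lists were COB of primary wall cellulose at -0.62 (adjusted p = 0.0616), and THI2.1 of the jasmonate list at 0.94 (adjusted p = 0.0712). Others were WSD1 at -0.41, MOL1 at 0.18, GI at -0.22, TZF8 at -0.21, ZAT10 at 1.31, CML38 at 1.30 and HTR10 of mature pollen at -0.05. None of these passed.

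The C3H15-OE counts rested on single arrays: they were 121 higher and 102 lower without WT replicate 1, 191 and 211 without WT replicate 3, 167 and 138 without C3H15-OE replicate 1, and 185 and 154 without C3H15-OE replicate 2. Without the 3 arrays that stood apart (C3H14-OE replicate 3, WT replicate 2 and mutant replicate 1), a choice made after the data were seen, they were 1204 and 1688.

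In the double mutant, which asked what the loss of both genes does, 2 of the 4 named xylan genes rose and the list did not pass with an estimated correlation (adjusted p = 0.118). IRX15L rose by 1.20 (SE 0.26, adjusted p = 0.0242) and IRX15 by 0.94 log2 units (SE 0.24, adjusted p = 0.0454), with IRX10 at 0.57 and IRX10L at 0.23. SBPASE rose by 1.28 (SE 0.23, adjusted p = 0.0129), the light-harvesting gene LHCB4.3 by 1.85 (SE 0.30, adjusted p = 0.00861) and NdhN, a subunit of the chloroplast NADH dehydrogenase-like complex, by 1.65 (SE 0.26, adjusted p = 0.00832). COR15B, a cold-induced chloroplast protein, rose by 1.40 (SE 0.22, adjusted p = 0.00839), whereas the cold-regulated COR27 fell by 2.21 (SE 0.34, adjusted p = 0.00769) and the clock gene GI by 0.69 (SE 0.13, adjusted p = 0.0143). The lignin enzyme HCT rose by 0.60 (SE 0.15, adjusted p = 0.0453) and CCOAMT (AT1G67980), named as a caffeoyl-CoA methyltransferase, fell by 1.82 (SE 0.44, adjusted p = 0.0365).

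The other large rises in the mutant were AT3G28270 (2.37), SIS (2.23), AT2G39110 (1.99), AT3G04540 (1.93), AT2G25625 (1.86), AT1G70820 (1.72), AT2G04039 (1.70) and TRY (1.62), a MYB repressor of trichome formation, with adjusted p-values from 0.000946 for AT2G04039 to 0.0283 for AT1G70820. The other large falls were AT2G05540 (-3.21), AT3G23550 (-2.85), AT1G10990 (-2.47), AT3G16530 (-2.23), AT1G52200 (-2.22), AT4G16000 (-2.11), AT4G33980 (-1.98) and AT5G44380 (-1.76), with adjusted p-values from 0.00357 for AT2G05540 to 0.0229 for AT1G52200. In all 575 probe sets were higher and 721 lower, of which 184 and 106 also passed 2-fold. After cyclic loess 58.7% of the calls were higher, against 44.4% as deposited.

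By list, the double mutant was shifted up for xylan (mean 0.74, camera adjusted p = 0.0013), photosynthesis (mean 0.71, adjusted p = 1.74e-05) and cold and abscisic acid (mean 0.95, adjusted p = 0.00803). With an estimated correlation the adjusted p was 0.118 for each of these lists, and by fry 0.0125 for each. Over all probe sets 2 of 4, 1 of 6 and 1 of 3 members were higher, and 3, 6 and 2 adjusted over the list alone. Lignin had 1 of 3 members higher both ways and did not pass by camera (adjusted p = 0.176, or 0.237 with an estimated correlation), though it did by fry (adjusted p = 0.0267). In the wall loosening list 0 of 4 members passed over all probe sets and 1, XTH16 at 1.33, did adjusted over the list alone (list adjusted p = 0.988). The mean of this list was 0.13, its median -0.15 and the direction of its test down. Its mean was -0.13 without WT replicate 2 and 0.36 without WT replicate 3. Of the dim tapetum and pollen wall genes 0 of 6 passed (A9 at 0.32 and RPG1 at 0.30, list adjusted p = 0.199). None of the flavonoid genes passed either (DFR at 0.22 and UF3GT at -0.20, list adjusted p = 0.988). Single members of other lists stood at 1.25 for the wax ester synthase WSD1 (adjusted p = 0.0587) and -0.52 for MOL1. They stood at -0.53 for WRKY53, 0.47 for THI2.1, 0.14 for COB, 0.11 for TZF8, 1.09 for CML38, -0.05 for ZAT10 and -0.02 for HTR10. None of these passed. The counts were 197 higher and 164 lower without WT replicate 1, 237 and 238 without WT replicate 2, and 264 and 356 without mutant replicate 3. The lower count was 469 without WT replicate 3 and 446 without mutant replicate 1. Fitted on the arrays of the mutant and WT alone they were 333 and 211, and without the 3 arrays that stood apart 244 and 139.

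**Figure D3:**
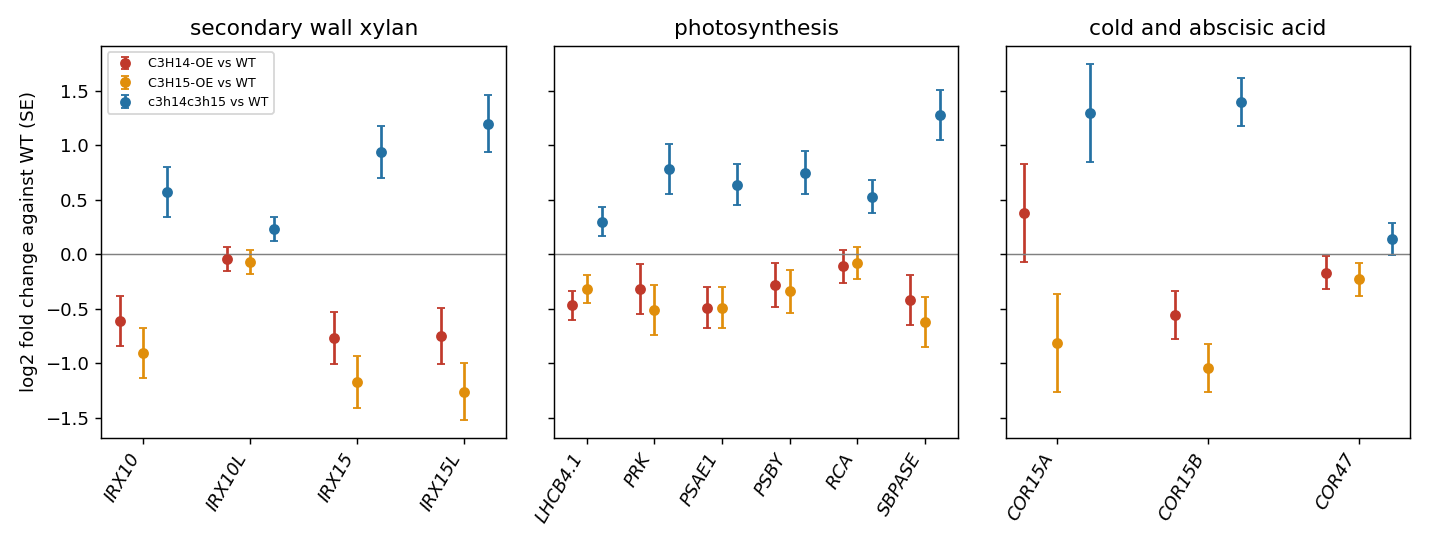
Log2 fold changes against WT, with SE, of every named member of the xylan, photosynthesis, and cold and abscisic acid lists in C3H14-OE, C3H15-OE and the double mutant. All 4 xylan genes lie below 0 in both overexpressors and above 0 in the mutant, IRX15L at -0.75, -1.26 and 1.20.

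Opposite responses to gain and loss were then counted: probe sets past the threshold one way in an overexpressor, the other way in the double mutant, and past it in the direct contrast. There were 58, of which 35 were lower in an overexpressor and higher in the mutant and 23 the reverse; 32 had 1 gene. The named ones lower with overexpression and higher in the mutant were AT3G14760 (C3H15-OE -1.61, mutant 1.41), AT4G33666 (-1.20, 1.35), IRX15L (-1.26, 1.20), COR15B (-1.04, 1.40), AT3G54040 (-1.21, 1.11), IRX15 (-1.17, 0.94), AT2G42770 (-1.18, 0.72) and AT5G47635 (-1.28, 0.95). AT4G27300 (1.17, -1.68) and AT3G28540 (1.30, -1.05) went the reverse way. AT2G42770 was the only one of these 10 to pass in C3H14-OE as well. Independent lists of the same sizes would share 42.8 probe sets in opposite directions between C3H15-OE and the mutant. By direction, 35 were lower in C3H15-OE and higher in the mutant against 20.5 for independent lists, and 23 the reverse way against 22.25. Both lists share the WT arrays, whose error favours overlap in the same direction over the opposite, so independent lists are not the no-change value. The count was 4 without WT replicate 1, 18 without WT replicate 2, 7 without WT replicate 3, 36 without C3H14-OE replicate 2, and 94 without C3H14-OE replicate 3. It was 17 without C3H15-OE replicate 1, 14 without C3H15-OE replicate 2, 101 without C3H15-OE replicate 3, 36 without mutant replicate 2 and 16 without mutant replicate 3.

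C3H15-OE and the double mutant also shared calls in the same direction, 45 higher in both and 65 lower in both, where independent lists would share 17.8 and 25.7. AT2G05540 and AT2G19970 were lower in both (AT2G19970 at -2.69 and -1.57) and SIS higher in both (2.25 and 2.23). How much of this the shared WT arrays bring was not measured, since 3 arrays cannot be split into parts of 2. Across probe sets, which are not independent replicates, the log2 fold changes of C3H14-OE and C3H15-OE correlated at 0.780 (simulated 0.405 ± 0.361 SD), with a covariance of 0.127 against 0.021 ± 0.024 simulated. C3H14-OE and the mutant correlated at 0.111 (simulated 0.482 ± 0.315; covariance 0.014 against 0.023 ± 0.023), and C3H15-OE and the mutant at 0.090 (simulated 0.423 ± 0.355; covariance 0.015 against 0.021 ± 0.023). Of the 4 probe sets higher in C3H14-OE all 4 were higher in C3H15-OE, and of the 6 lower 5 were lower, where independent lists would share 0.12 and 0.21. Of the same 6, 2 were lower in the mutant and 1 was higher, where independent lists would share 0.19 and 0.15.

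**Figure D4:**
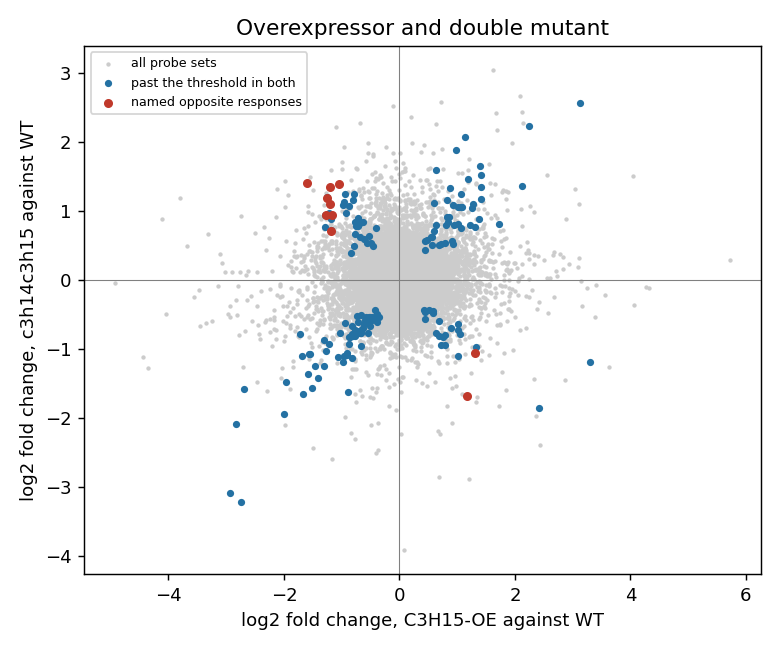
Log2 fold change against WT in C3H15-OE (horizontal) and in the double mutant (vertical) for all probe sets in grey, those past the threshold in both in blue, and the 10 named opposite responses in red. Opposite responses lie in the upper left and lower right; 45 and 65 probe sets lie in the upper right and lower left.

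Set directly against each other, the overexpressors differed in 28 probe sets. AT1G50040 (1.74, SE 0.20, adjusted p = 0.0168), AT5G05890 (1.30), TRM28 (1.29), AT2G20670 (1.08) and AT1G31040 (1.03) were higher in the arrays labelled C3H14-OE. QQS (-3.47, SE 0.53, adjusted p = 0.0364), MSRB9 (-2.52, SE 0.25, adjusted p = 0.0098), AT4G00700 (-1.97), AT1G53980 (-1.26) and AT2G39710 (-1.12) were higher in C3H15-OE. There were 14 probe sets each way, and 0 of the 7 lists fixed beforehand passed (lowest adjusted p = 0.112, for xylan and for cold and abscisic acid), with IRX15L at 0.51 and IRX15 at 0.40. Both of these lists passed by camera without C3H15-OE replicate 3 (adjusted p = 0.00189 and 0.0126). With all arrays and an estimated correlation the adjusted p was 0.473 for each. Fitted on these 6 arrays alone limma called 0, where 2226 had an unadjusted p under 0.05 in the joint fit. The counts higher and lower were 71 and 29 without C3H14-OE replicate 3, and 83 and 100 without C3H15-OE replicate 3. They were 3 and 2 without WT replicate 1, 6 and 6 without WT replicate 2, and 6 and 3 without WT replicate 3. They were 0 and 2 without C3H14-OE replicate 1, 1 and 1 without C3H14-OE replicate 2, 0 and 3 without C3H15-OE replicate 1, 0 and 0 without C3H15-OE replicate 2, and 5 and 2 without mutant replicate 3. They were 24 higher without mutant replicate 1, and 189 and 63 without the 3 arrays that stood apart.

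The mean of both overexpressors against the double mutant gave the most calls. This contrast leaves out the WT mean, though the WT arrays entered the shared estimate of spread. It sets 6 arrays against 3, so its SEs were smaller (for C3H14 0.39, against 0.45 in the comparisons with WT). AT4G16260 was higher with overexpression by 5.27 (SE 0.80, adjusted p = 0.00113), as were the defensins PDF1.2b by 5.05 (SE 0.81, adjusted p = 0.00144) and PDF1.2 by 4.52 (SE 1.52, adjusted p = 0.0478), AT3G23550 by 4.43 and AT3G16530 by 3.29. The PDF1.2b probe set is of a kind that can also bind related transcripts, and PDF1.2 varied within both overexpressor groups (SD 3.57 and 3.72, n = 3 each), with C3H14-OE replicate 3 5.95 above the other C3H14-OE arrays. AT5G22580 (-3.52), AT5G63180 (-3.23), a pectate lyase, P1R1 (-3.12), AT5G44680 (-3.08) and the gibberellin-regulated family member AT1G22690 (-2.81) were lower, with adjusted p-values from 0.00164 to 0.0209. All 4 xylan genes were lower, IRX15L by -2.21 (SE 0.23, adjusted p = 0.000202), IRX15 by -1.91, IRX10 by -1.34 and IRX10L by -0.29 (adjusted p = 0.0498). All 6 photosynthesis genes were lower.

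In this contrast 3072 probe sets were higher and 2725 lower, 441 and 610 of them also past 2-fold. Camera gave adjusted p-values of 0.000286 for xylan (mean -1.43), 1.41e-05 for photosynthesis (mean -1.09) and 0.0084 for cold and abscisic acid (mean -1.35; 2 of 3 members lower, and 3 adjusted over the list alone), and 0.114 for each with an estimated correlation. By fry they were 0.000182 for xylan, 0.000252 for photosynthesis and 0.000182 for cold and abscisic acid. The flavonoid, lignin, tapetum and pollen wall, and wall loosening lists did not pass (adjusted p = 0.9, 0.498, 0.498 and 0.781), though HCT (-0.50) and XTH16 (-2.43) were lower and EXPA4 (0.78) higher. Among single members WRKY53 (2.14), ZAT10 (1.66), MOL1 (0.60) and GI (0.50) were higher and WSD1 (-1.66) and COB (-0.61) lower. Leaving out mutant replicate 2 lowered the higher count to 2032.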

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

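The tests of a wrong label, of time of day, of linked sequence, of water deficit or heat and of the within-group axis in the mutant alone were set, or had their reading set, only after the values behind the pattern were seen; the counts of other splits and the test of that axis on gain against loss were planned before theirs.

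The response to overexpression differed between C3H14-OE and C3H15-OE by the direct contrast at 28 probe sets, which is a difference between groups. In C3H14-OE minus C3H15-OE, AT1G50040 stood at 1.74, AT5G05890 at 1.30, TRM28 at 1.29, AT2G20670 at 1.08, AT1G31040 at 1.03, QQS at -3.47, MSRB9 at -2.52, AT4G00700 at -1.97, AT1G53980 at -1.26 and AT2G39710 at -1.12. Responses went opposite ways in an overexpressor and in the double mutant at 58 probe sets. Groups of 3 arrays were not tested for outliers.

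Fitted on the arrays compared alone, C3H14-OE against WT gave 39 probe sets and the highest of the other splits 0, C3H15-OE against WT 1686 and 0, and the mutant against WT 544 and 0. In each of these the real split was the 1 with as many, and with 10 splits the share cannot fall under 0.1. For C3H14-OE against C3H15-OE the real split gave 0 and the highest other 2, so that all 10 splits gave as many, again with too few splits for a share under 0.05. For the mean of the overexpressors against the mutant the real split gave 5355 and the highest other 15. That was 1 of 84 splits, so a random grouping of these arrays is an unlikely source of the count. Every other split mixes overexpressor and mutant arrays, so the count does not tell the genes from other differences between the groups.

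The array labelled C3H14-OE replicate 3 lay near the C3H15-OE arrays on principal component 1 but at -42.5 on component 3, where they lay at 16.5, 23.1 and -5.2, and had 167 probe sets over 4-fold from the rest of its group, against 8 to 82 on the other 11 arrays. On 200 probe sets chosen without it, its median position was 0.54 between C3H14-OE (0) and C3H15-OE (1). That lay inside the range of held-out C3H15-OE arrays (0.36 to 0.84), while the other C3H14-OE arrays, held out likewise, stood at 0.01 and 0.14. Its C3H14 level lay 3.7 SDs above the C3H15-OE mean, so a wrong label cannot be told apart from a C3H14-OE plant, in either case in a state not shared by the C3H15-OE arrays. A candidate explanation is water deficit or heat: AT3G17520 (4.58), AT3G02480 (4.00), AT1G53540 (3.85), AT2G29500 (3.69), LEA4-5 (3.53) and AT1G54050 (3.47) stood above the other C3H14-OE arrays, and above the C3H15-OE mean too (4.49, 4.01, 3.51, 3.71, 3.51 and 3.48), but these 6 late embryogenesis and small heat shock genes had been seen before the list was written and were left out of its test. Of the 22 remaining members 2 lay over 1 log2 unit above (AtLEA4-1 at 1.74 and AT3G15670 at 1.12), against 0 on every other array. Of 1000 random lists of that size 47 had as many or more, and the median deviation of the 22 members was 0.02, so the evidence is thin; C3H14 stood at 7.07 on this array, within the WT range and lowest in its group, so more C3H14 is not seen there, and no other biological explanation was tested.

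The C3H15-OE and C3H14-OE counts may also reflect a growth stage or handling difference that varies within groups. The main within-group axis (28.6% of that variance) correlated across probe sets, which are not independent, at 0.502 in size with the log2 fold changes of gain against loss, above the 95th percentile of random directions (0.45; 9 of 1000 at or above). With the array scores on this axis as a covariate, C3H15-OE calls went from 1513 to 23 (median size 0.89 to 0.59, SE 0.19 to 0.22), C3H14-OE calls from 10 to 3 (1.76 to 1.63, SE 0.20 to 0.24), those between the overexpressors from 28 to 90, and those of gain against loss from 5797 to 2478, more than the tenth set in advance as the bound. The axis holds the differences of C3H15-OE (r = 0.666) and C3H14-OE (r = 0.667) from WT as well, so it and an effect of either gene cannot be told apart. With the mutant fold changes the axis had an r of 0.065, a usual value: 579 of 1000 random directions gave as much or more (median 0.077). Its mean scores were close in WT and the mutant (-21.3 and -17.8). The median size of the mutant calls stood at 0.68 and 0.69 without and with the covariate (SE 0.14 in both). These values argue against this axis as the cause of the mutant calls, but not against growth or handling differences off it. The number of mutant calls went from 1296 to 2093. That rise is no support, since the covariate was built to take up within-group variance.

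For the double mutant, sequence linked to the mutated loci and harvest at another time of day were weighed. Within 200 genes of either locus 11 of 208 named genes were called (5.3%), against 178 of 3202 elsewhere on chromosome 1 (5.6%; odds ratio 0.95, 95% interval 0.46 to 1.78, Fisher's exact test, two-sided p = 1). The windows hold few of the named genes, so most calls would lie away from the loci in any case. The interval includes both a lower and a higher share near the loci, and linkage stays open for the 11 near them, CCOAMT among them. GI, the 1 named gene of the clock lists, stood at -0.69, and its size plus 2 SE (0.95) was under the bound of 1.11 taken from COR27. That bound assumed that GI and COR27 swing alike over a day, and GI itself passed the threshold, so time of day may contribute and cannot be told apart from the loss of both genes, which the design names.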

How the results depend on the processing

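Leaving out 3 arrays that stood apart was chosen only after the data were seen; the other alternatives were planned. No called result changed direction where direction was checked. For named genes with single arrays left out, that was only at the array whose removal gave the highest adjusted p. The correlations of the mutant with either overexpressor crossed 0 without single arrays. Where a count moved by over 1.5 times or a call was gained, the cause was not tested, except that fewer probe sets or arrays were in the test where the setting says so. Counts are given as higher and lower.

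For C3H14-OE against WT (4 and 6), cyclic loess gave 2 higher, the arrays compared alone 16 and 23, the replicate block 1 and 3, array weights 18 and 29, 1-gene probe sets without shared suffixes 1 and 3, 1 probe set per gene 1 and 3, and leaving out the 3 arrays 48 and 142. For C3H15-OE (702 and 811), the block gave 535 lower, weights 1366 and 1596, 1-gene probe sets 307 and 381, 1 per gene 309 and 385, the 3 arrays out 1204 and 1688, and the 2-fold threshold 273 and 345. For the mutant (575 and 721), the arrays compared alone gave 333 and 211, weights 365 and 381, 1-gene probe sets 267 and 384, 1 per gene 265 and 385, the 3 arrays out 244 and 139, and 2-fold 184 and 106. For C3H14-OE against C3H15-OE (14 and 14), loess gave 24 higher, leaving out the dimmest 40% 7 lower, the arrays compared alone 0 and 0, the block 7 and 8, weights 536 and 345, the 3 arrays out 189 and 63, and 2-fold 9 higher. For gain against loss (3072 and 2725), 1-gene probe sets gave 1576 and 1416, 1 per gene 1575 and 1429, and 2-fold 441 and 610. Opposite responses (58) were 37 with the block, 29 with 1-gene probe sets, 29 with 1 per gene and 10 with 2-fold. C3H14 passed the threshold in C3H15-OE with weights (-1.50) and with the 3 arrays out (-1.70), also without C3H14-OE replicate 3 (-1.34), and in C3H14-OE against C3H15-OE with loess (2.68), weights (3.18), 1-gene probe sets (2.68), the 3 arrays out (3.24), and without C3H14-OE replicate 3 (3.24) or C3H15-OE replicate 3 (2.91).

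Without each array in turn, the counts ranged from 0 to 19 and 1 to 37 for C3H14-OE, 121 to 891 and 102 to 1128 for C3H15-OE, 197 to 696 and 164 to 738 for the mutant, 0 to 83 and 0 to 100 for C3H14-OE against C3H15-OE, 2032 to 3097 and 1819 to 2803 for gain against loss, and 4 to 101 for opposite responses. C3H14 ranged from 0.90 to 1.91 in C3H14-OE, -1.70 to -1.05 in C3H15-OE, -0.87 to -0.21 in the mutant and 2.23 to 3.24 between the overexpressors. The correlations of fold changes ranged from 0.688 to 0.827, -0.095 to 0.258 and -0.117 to 0.234. Of the 74 named entries 37 lost their call without at least 1 array. At the array whose removal gave the highest adjusted p, 0 changed direction. The 10 opposite responses were judged here on gain against loss alone, so losses of their calls against WT are not in the 37. Calls were also lost by 11 of the 74 with the replicate block, 17 with the arrays compared alone and 7 with an intensity trend and robust eBayes. Cyclic loess put 58.7% of the mutant calls and 28.6% of the C3H14-OE calls higher, against 44.4% and 40% as deposited. Signal over background could not be read from summarised intensities, so dim probe sets limit the calls to an unknown degree.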

Other observations

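The lists described here are among 24 added after the annotation was seen, so they were not among those fixed before the data were examined, and all camera and fry p-values are adjusted over these 24. By camera 7 of the 24 passed in C3H15-OE and 4 in the mutant, and 0 with an estimated correlation. Not all are described. The 15 IQ-domain proteins also shifted down in C3H15-OE (14 below 0, camera adjusted p = 0.00122, 0.298 with an estimated correlation, 0.00772 by fry). They did so in C3H14-OE too (13 below 0, camera adjusted p = 0.00144, 0.29 with an estimated correlation, 0.0483 by fry). In C3H15-OE the secondary wall coexpressed list of 31 named genes, 4 of them also in the xylan list, shifted down (mean -0.64, adjusted p = 3.47e-08, or 0.298 with an estimated correlation). In it 9 members fell, AT2G03200 (-1.39), AT2G31930 (-1.29) and AT2G41610 (-1.27) among them, 1 rose (PME61 at 0.77) and 21 did not pass. The 7 tubulins also shifted down (mean -0.90, adjusted p = 0.000287, or 0.298 with an estimated correlation), with TUB1 (-2.46), TUB5 (-1.22), TUB6 (-0.97) and TUA6 (-0.88) lower and 3 not past the threshold. All 7 lay below 0 in C3H14-OE as well, with 0 past the threshold. Their mean there was -0.53 (camera adjusted p = 0.00218, 0.38 with an estimated correlation, 0.0677 by fry). Of 10 xyloglucan endotransglucosylases XTH16 (-2.12) and XTH32 (-1.08) were lower in C3H15-OE and 8 did not pass (adjusted p = 0.0068, or 0.248 with an estimated correlation). By fry the adjusted p in C3H15-OE was 0.0153 for the secondary wall coexpressed list, 0.00772 for the tubulins and 0.00097 for the xyloglucan endotransglucosylases.

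In the double mutant the secondary wall coexpressed list shifted up by camera (mean 0.54, adjusted p = 8.75e-08). It did not pass with an estimated correlation (adjusted p = 0.38) or by fry (adjusted p = 0.119). In it GH9B5 (1.45), IRX15L (1.20), IRX15 (0.94) and AT1G31720 (0.86) rose, 27 did not pass, and 30 of 31 lay above 0. Among 14 SWEET sugar transporters SWEET13 (1.59) and SWEET1 (1.06) rose and SWEET16 (-1.07) fell (camera adjusted p = 0.0402, or 0.245 with an estimated correlation and 0.000529 by fry). SWEET13 was dim in WT (3.08). SWEET16 also fell in C3H15-OE against the same WT arrays (-1.56, adjusted p = 0.0118).

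Between the overexpressors, the secondary wall coexpressed list was higher in C3H14-OE than in C3H15-OE (mean 0.35, 27 of 31 members above 0, camera adjusted p = 8.3e-06, or 0.538 with an estimated correlation and 0.39 by fry), with 0 members past the threshold. This mean was 0.18 without C3H15-OE replicate 2 and 0.53 without C3H15-OE replicate 3. Against WT the list was lower in C3H14-OE (mean -0.30, 26 of 31 members below 0, camera adjusted p = 0.00144, or adjusted p = 0.455 with an estimated correlation and 0.189 by fry). The 69 chloroplast genome transcripts shifted up against WT by camera in all 3 groups, with 0 members past the threshold by limma. By fry the list did not pass (adjusted p = 0.485 in C3H14-OE, 0.27 in C3H15-OE and 0.764 in the mutant). Its estimated inter-gene correlation was 0.713, so its members moved largely together and are not 69 separate pieces of evidence. These comparisons share the WT arrays, so an error in those arrays would move all 3 groups the same way. The mean of these transcripts was 0.54 in C3H14-OE (camera adjusted p = 2.14e-10, or adjusted p = 0.486 with an estimated correlation). It was 0.63 in C3H15-OE (adjusted p = 2.56e-09, or adjusted p = 0.583) and 0.225 in the mutant (adjusted p = 0.0193, or adjusted p = 0.861). In the mean of the overexpressors against the mutant it was 0.36, with 1 member lower. There the camera adjusted p was 0.0247, or 0.684 with an estimated correlation and 0.5 by fry.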
